A study of Mus musculus with 8 samples.

How the data were processed

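RNA from whole mouse kidneys dissected at E13.5 was compared between wild type embryos and mutants lacking HDAC1 and HDAC2 in the ureteric bud (UB), the epithelial outgrowth that branches into the collecting duct system. Per the labels, 0.5 µg of total RNA per sample was labelled with Cy3 or Cy5, and each of 4 biological replicates (1 mutant and 1 wild type RNA) was hybridised on 2 arrays with the dyes exchanged, which gives 8 arrays. The deposited scanner files place replicates 1 and 2 on 1 slide and replicates 3 and 4 on another. Per the file headers, the authors scanned two-colour Agilent mouse arrays and extracted the spots with Feature Extraction 10.5.1.1. The deposited intensity columns hold the median brightness of each spot and of its local background, with no normalization, and the processed signals, which were background-subtracted and dye-normalized by the scanner software. The deposited log ratio of each spot is the log10 of red (Cy5) over green (Cy3) processed signal, per the file headers. The deposited flags for spots well above background, saturated or outlying are 0 or 1, of no other unit. The authors' deposited table holds 496 entries with 1 log2 ratio each, which fall on 494 features of the array, selected at p 0.05 and 1.4-fold with MeV 4.9, per the name they gave it, and states no direction for the ratio.

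Each array held 45018 spots, of which 1639 were controls. Median spot signals were background-corrected with limma's normexp method at an offset of 50, in place of the mean signals that had been planned, which the deposited files do not hold. Log2 ratios were normalized within each array by loess, with control and outlier spots at weight 0, and spots of a probe were averaged. The ratio of each array was turned to the channel labelled mutant over the channel labelled wild type, and the 2 arrays of a replicate were averaged, so that dye effects cancel and each replicate counts once. Probes were kept when well above background in at least 1 channel on at least 4 of the 8 arrays, which left 39520 of 41174 probes. Accessions of 25097 probes matched a symbol in the RefSeq table of GRCm38.p6, used for names only, and the others kept the accession or identifier of the array. The array design cites another genome build, so no positions are given. The probe with the highest mean log2 intensity stood for its gene, which gave 31183 genes with values in at least 3 replicates, 17113 of them named. No spot was saturated. Per array, between 79.2% and 97.1% of the spots were well above background in the channel labelled wild type, and between 82.1% and 95.9% in the channel labelled mutant. The number of arrays limits the precision.

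The replicate log2 ratios were tested against 0 with limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3), with Benjamini-Hochberg adjustment over all genes at a threshold of 0.05, and all tests were two-sided. Within the 4 pairs, the deviations of the mutant and the wild type RNA from their group means were correlated across genes at 0.535 to 0.768 in separate channels. Each RNA labelled mutant correlated best with its partner on the same arrays. Partners share their arrays, so this shows a pairing by hybridisation and cannot tell whether the RNAs were matched in other ways. The ratio keeps the pairing by array. Before the data were examined, 32 gene lists were fixed, 7 of them primary, and tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. At the preset correlation, camera sets a list against the other genes, with degrees of freedom from the number of genes. Its p then does not measure the spread over the 4 replicates. At an estimated correlation the degrees of freedom come from the 4 replicates, which makes a call harder. Members of a list were also adjusted over the list alone. The lists were UB tip and Ret signalling, UB stalk and epithelial trunk, nephron progenitors, committed nephron epithelium, p53 targets, Wnt/beta-catenin targets and cell cycle as primary lists, and collecting duct, podocytes, proximal tubule, loop of Henle and distal tubule, stroma, endothelium, erythroid cells, macrophages, neurons and glia, adrenal cortex and gonad, skeletal muscle, Wnt ligands and receptors, CDK inhibitors, apoptosis regulators, other histone deacetylases, HDAC1/2 corepressor subunits, REST targets, germline genes, Hox genes, kidney injury, the renin-angiotensin and bradykinin systems, extracellular matrix, immediate early and heat shock genes, hypoxia and glycolysis, and sex-linked genes.

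Named genes followed a rule fixed before the data were examined: Hdac1 and Hdac2, the 12 largest changes in each direction past the adjusted threshold with the same sign in 4 of 4 replicates, filled where fewer pass with the smallest unadjusted p among genes at p under 0.05 and at least 1.4-fold, and from each list up to 4 members that pass or, if none does, the 2 of smallest p. Members that pass over a list alone are named beside them as examples chosen after their values were seen. The match of accessions used here named no probe Hdac1, and 16077 probes stayed without a name, so Hdac1 is not analysed here. Some list members that the rule names are not reported here, without replacement, and stay in the tests of their lists. Where the Hdac2 probe lies against the deleted part of the gene is not given in the sources used here.

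The steps after normalization were tested on simulated ratios with the real spread and dye effects of 31041 genes, for the comparison of labelled mutant with labelled wild type. Background correction, loess, the averaging of spots and the choice of probe were not covered. Noise was drawn for each gene independently, so structure that genes share on the real arrays was not covered either. Of 66 genes changed 1.4-fold, 6.06% passed the adjusted threshold, against 61.2% of 67 genes changed 2-fold and 92.5% of 67 genes changed 4-fold. Of 30814 unchanged genes, 6 passed. Alternatives covered the background correction, the normalization, the filter, the choice of probe, the 8 arrays with and without the replicate as a block, each dye orientation alone, separate channels without pairing, array weights, the slide, each replicate left out, and a plain one-sample t statistic without limma's moderation. Plots were drawn with matplotlib 3.10.9.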

Results

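The expression of 31183 genes was measured in whole kidneys of E13.5 embryos, when the ureteric bud branches inside the mesenchyme that forms the nephrons. Of these genes, 17113 were named, and the others are accessions or identifiers of the array, each counted as a gene. The study compared wild type kidneys with kidneys that lack the histone deacetylases HDAC1 and HDAC2 in the ureteric bud, in 4 biological replicates, each with 1 RNA per genotype hybridised in both dye orientations. On each array, between 82.1% and 95.9% of the spots were well above background in the RNA labelled mutant, and between 79.2% and 97.1% in the RNA labelled wild type. The comparison asks which transcripts of the kidney differ when the bud lacks both enzymes.

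Hdac2, the measured one of the deleted genes, did not show the loss that the labels name. Its log2 ratio of the RNA labelled mutant over the RNA labelled wild type was 0.45, 0.40 and 0.61 in replicates 1 to 3 and -0.43 in replicate 4, with the same sign on both arrays of each replicate. The mean was 0.26 ± 0.47 (SD, n = 4; exact sign-flip permutation p = 0.375, where 4 replicates allow no p under 0.125), and limma's adjusted p was 0.804. Leaving out each replicate in turn gave means from 0.14 without replicate 3 to 0.49 without replicate 4. Whole kidney RNA also holds Hdac2 from the cells outside the bud. Hdac1 is not analysed here.

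**Figure D1:**
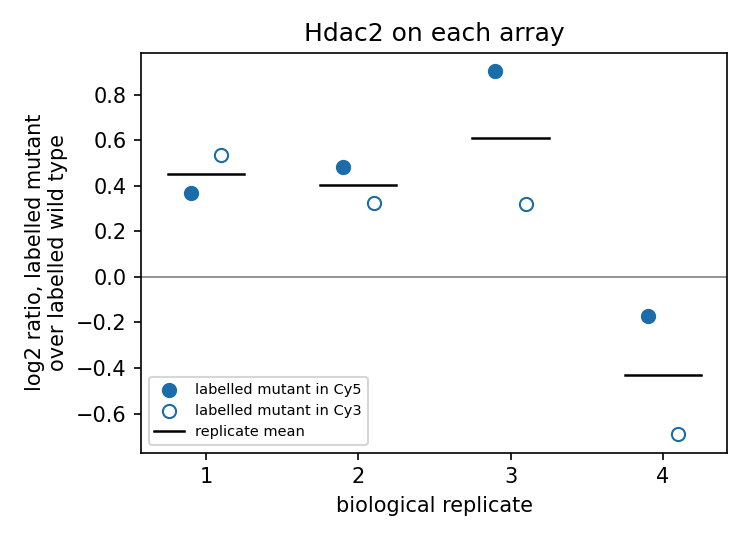
Log2 ratio of Hdac2 (y axis) in the RNA labelled mutant over the RNA labelled wild type on each of the 8 arrays, by biological replicate (x axis). Filled points are arrays with the labelled mutant in Cy5, open points those with it in Cy3, and bars are replicate means, which lie between 0.40 and 0.61 in replicates 1 to 3 and at -0.43 in replicate 4.

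The direction of all ratios is open. The authors' deposited table gives ratios of the same size as the mean scanner ratio over the 8 arrays but of the opposite sign: 463 of its 496 entries equal the sign-turned value within a tolerance of 0.01 (log2), and 0 entries equal it as labelled. Of the 266 entries whose identifier has 1 spot on the array, 266 have the opposite sign. Aldh1a3, for example, has a log2 ratio of 0.97 in the authors' deposited table and a scanner log2 ratio of -0.98 by the dye labels. The table does not say which genotype stands above the other. All signs here follow the dye labels, and "labelled mutant" and "labelled wild type" name the channels. If the authors' deposited table is written as mutant over wild type, every sign would turn. If it is written as wild type over mutant, none would.

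No single gene passed over all genes, while a list of genes of the bud stalk shifted in camera (adjusted p = 2.4e-17), but not with an estimated correlation (0.175) or with fry (0.0531). Among the named genes, Srrm3 stood 3.34-fold and Pinx1 2.57-fold lower in the RNA labelled mutant. In the same RNA, Cdh16 (the cadherin of kidney tubule epithelium) stood 2.51-fold, Fxyd4 (a regulator of the sodium pump in the collecting duct) 2.47-fold and Tfcp2l1 (a transcription factor of the collecting duct) 1.94-fold above the RNA labelled wild type. Stra6 (the receptor that takes up retinol) stood 2.24-fold and Aldh1a3 (an enzyme of retinoic acid synthesis) 1.92-fold below it. None of these passed the adjusted threshold over all genes. Each had 1 sign in 4 of 4 replicates, which their choice by small p over the same replicates favours. Another probe of Pinx1 stood at a log2 ratio of 0.29. The probes of Srrm3 ranged from -1.74 to -0.00 and those of Tfcp2l1 from 0.07 to 0.95. The bud stalk list holds keratins and claudins. These signs would turn if the authors' deposited table is written as mutant over wild type.

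Over all genes, limma called 0 genes higher and 0 lower in the RNA labelled mutant, with a smallest adjusted p of 0.114. At an unadjusted p under 0.05 there were 1839 genes, 1015 higher and 824 lower, against 1559 expected by chance. Of these, 107 genes were at least 1.4-fold higher and 117 at least 1.4-fold lower. A plain one-sample t statistic on the same values also gave 0 genes after adjustment and 1789 at an unadjusted p under 0.05. The median SD of a gene's replicate ratios was 0.17 (log2), and 14.5% of the genes had 1 sign in 4 of 4 replicates, where chance gives 12.5%. The count of calls depended on how replicates were weighed. With all 8 arrays and the replicate as a block, limma called 58 genes higher and 16 lower, and with array weights 58 and 20. The block had a consensus correlation of -0.026, so the arrays of a replicate counted almost as independent samples. Without replicate 2, which had the lowest array weight (0.23), limma called 9 and 2. The dye orientations of replicate 2 correlated at 0.70 across genes, against 0.07, -0.28 and -0.30 in replicates 1, 3 and 4. Its low weight thus does not mark disagreement between its arrays. Without replicate 3, 893 genes were at an unadjusted p under 0.05, and without replicate 1, 338 genes were at least 1.4-fold lower at that p.

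None of the 12 named genes above 0 passed. Cdh16 had a log2 ratio of 1.33 ± 0.21 (SD, n = 4), Fxyd4 1.30 ± 0.22, and Gsta3, a glutathione transferase, 1.15 ± 0.16. Lrrc4 stood at 1.00 ± 0.19, Mia, a small secreted protein, at 0.98 ± 0.10, Tfcp2l1 at 0.95 ± 0.15, and Rgn, the calcium-binding protein regucalcin, at 0.88 ± 0.08. Tm4sf20 stood at 0.82 ± 0.13, Grb7, an adaptor of receptor tyrosine kinases, at 0.80 ± 0.14, and Scin, an actin-severing protein, at 0.68 ± 0.10. Hkdc1, a hexokinase family member, stood at 0.66 ± 0.02 and Slc32a1, a vesicular transporter of GABA and glycine, at 0.59 ± 0.06. Their adjusted p in limma was 0.114 for 7 of them and at most 0.165. The probes of Tfcp2l1 ranged from 0.07 to 0.95, of Mia from 0.98 to 1.55 and of Gsta3 from 0.91 to 1.15. In the scanner ratios Rgn stood at 1.51.

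The 12 named genes below 0, none of which passed, included Srrm3 at -1.74 ± 0.57 (SD, n = 4) and Pinx1, an inhibitor of telomerase, at -1.36 ± 0.46. Stra6 stood at -1.16 ± 0.30, Aldh1a3 at -0.94 ± 0.10, Adamts18, a secreted protease of the bud tips, at -0.90 ± 0.13, and Lyzl1 at -0.88 ± 0.21, with a signal well above background on 5 of 8 arrays in the RNA labelled mutant. The size of the Lyzl1 log2 ratio depends on the processing. It was -1.15 at an offset of 16 and -2.05 in the scanner ratios, which differ in both background correction and normalization. Tcea3, an elongation factor of RNA polymerase II, stood at -0.80 ± 0.18 and Inhbb, an activin subunit, at -0.77 ± 0.17. Rxfp3, the relaxin-3 receptor, stood at -0.54 ± 0.16, Pakap at -0.53 ± 0.16, Rexo1 at -0.51 ± 0.10 and Prrx1, a homeobox factor of mesenchyme, at -0.50 ± 0.12. Other probes of Pinx1 (up to 0.29), Pakap (up to 0.11) and Rexo1 (up to 0.07) had the opposite sign, and the probes of Srrm3 ranged from -1.74 to -0.00, of Inhbb from -0.77 to -0.21, of Prrx1 from -0.59 to -0.08 and of Tcea3 from -0.80 to -0.67. In limma's blocked fit of the 8 arrays 20 of the 24 named genes passed, and with array weights 22. The blocked fit had a consensus correlation of -0.026, so it counted the arrays of a replicate almost as independent samples. None of these 24 changed sign under an alternative that gave it a value, and the strict filter removed Lyzl1. All replicates of each gene share a sign, so leaving out or reweighing replicates could not turn it.

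**Figure D2:**
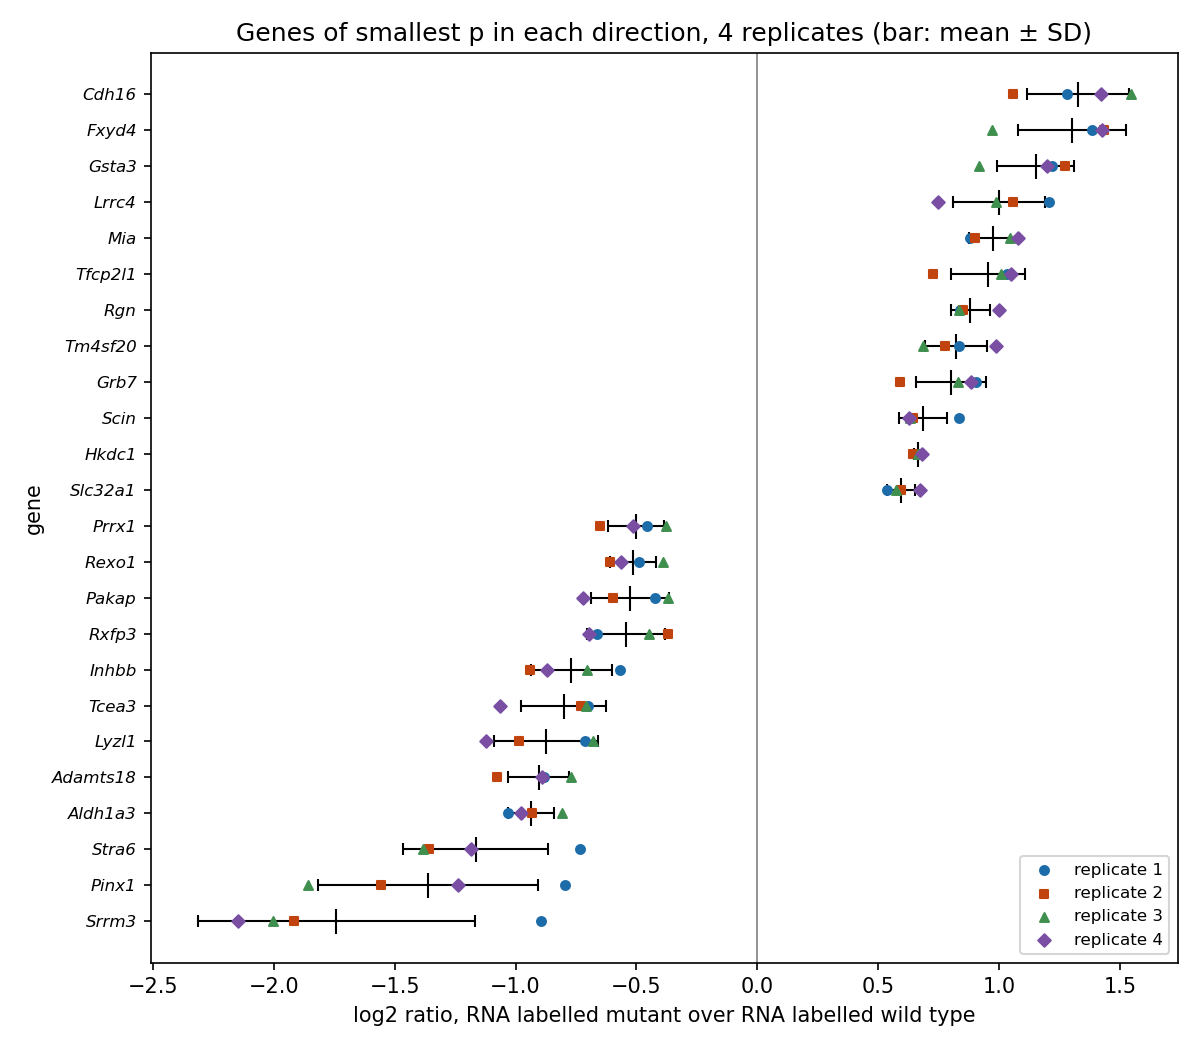
Log2 ratio (x axis) of the RNA labelled mutant over the RNA labelled wild type for the 12 named genes on each side of 0 (y axis). Symbols are the 4 replicates, and black bars the mean ± SD. All 4 replicates of each gene lie on 1 side of 0, from Cdh16 at a mean of 1.33 to Srrm3 at -1.74.

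The list of bud stalk and epithelial trunk genes rose in the RNA labelled mutant in camera. Its adjusted p was 2.4e-17, but 0.175 with an estimated correlation and 0.0531 with fry. Of its 28 measured members, 24 were above 0 and 4 below, with a median log2 ratio of 0.32, and 17 were higher and 1 lower when adjusted over the list alone. The simple epithelial keratins were among them, Krt18 at 1.03 ± 0.33 (SD, n = 4), Krt7 at 0.96 ± 0.29 and Krt8 at 0.85 ± 0.19, with Tfcp2l1 and the transcription factor Elf5 at 0.83 ± 0.17. So were the calcium-binding protein Calb1 at 0.79 ± 0.20, the adhesion molecules Epcam at 0.67 ± 0.14 and Cdh1 at 0.37 ± 0.06, and the tight junction protein Cldn3 at 0.59 ± 0.17. Aldh1a3 was the 1 lower member, while Wnt9b stood at -0.17 ± 0.70 and Wnt7b at 0.00 ± 0.26. The median of the list was above 0 on 8 of 8 arrays, at 0.33 within slide 1 and 0.31 within slide 2.

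Genes of the bud tip and of Ret signalling did not move as a list. Of 23 measured members, 13 were above 0 and 10 below (median log2 ratio 0.05, or 0.0336 to 0.0851 with each replicate left out, camera adjusted p = 0.141, and 0.440 with an estimated correlation). Over the list alone, Kcnk1 at 0.48 ± 0.20 (SD, n = 4), the receptor Met at 0.36 ± 0.15 and Wnt11, a Wnt ligand of the tips, at 0.32 ± 0.14 were higher and Adamts18 was lower. Ret itself, the receptor that drives branching, stood at -0.07 ± 0.25 and its coreceptor Gfra1 at 0.14 ± 0.17. The list would have passed with median centring in place of loess, at a median of 0.17. Among 18 collecting duct genes, 10 were above 0 (median 0.01, camera adjusted p = 0.0515), and Fxyd4 and the sodium channel subunit Scnn1g, at 0.50 ± 0.22, were higher over the list alone.

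Committed nephron genes rose in the RNA labelled mutant as a list, and nephron progenitor genes did not pass. Of 24 committed nephron genes, 19 were above 0 (median log2 ratio 0.15, camera adjusted p = 8.6e-05, but 0.175 with an estimated correlation), on 8 of 8 arrays. On the arrays with the labelled mutant in Cy3 alone the list did not pass (camera adjusted p = 0.0964). None of them passed over the list alone. The Notch target Hes5 stood at 0.66 ± 0.40 (SD, n = 4) and Wnt4, a signal of the mesenchyme's conversion to epithelium, at 0.34 ± 0.18. Within slide 1 the median was 0.15 and within slide 2 it was 0.09. Of 24 nephron progenitor genes, 8 were above 0 and 16 below (median -0.07, or -0.0889 to -0.0326 with each replicate left out, camera adjusted p = 0.365), with Wt1 at -0.30 ± 0.11 and Dapl1 at 0.24 ± 0.03. With median centring alone in place of loess the Nephron progenitors list passed in the other direction (median 0.16, camera adjusted p = 0.0341), and within slide 2 its median was 0.00.

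Wnt/beta-catenin targets rose as a list in the RNA labelled mutant. Of 27 measured genes, 19 were above 0 (median log2 ratio 0.15, camera adjusted p = 3.4e-05, and 0.175 with an estimated correlation), on 8 of 8 arrays. On the arrays with the labelled mutant in Cy3 alone the list did not pass (median 0.09, camera adjusted p = 0.136). Over the list alone, the feedback regulators Rnf43, at 0.54 ± 0.15 (SD, n = 4), and Axin2, at 0.49 ± 0.13, the transcription factor Lef1, at 0.44 ± 0.13, and Tnfrsf19, at 0.37 ± 0.19, were higher, and the repressor Tcf7l1, at -0.30 ± 0.13, was lower. Within slide 1 the median was 0.15 and within slide 2 it was 0.08. Of 33 Wnt ligands and receptors, 20 were above 0 (median 0.05, camera adjusted p = 0.0143, and 0.219 with an estimated correlation), with 3 higher over the list alone. These were the receptors Fzd10 at 0.62 ± 0.17 (SD, n = 4), whose other probe stood at -0.02, and Fzd4 at 0.37 ± 0.08, and the ligand Wnt10a at 0.50 ± 0.19. The list missed the threshold without replicate 1 (camera adjusted p = 0.0503) and without replicate 4 (0.0512). The median of the ligands and receptors turned to -0.03 on the arrays with the labelled mutant in Cy3.

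Cell cycle genes rose slightly as a list, and p53 targets did not shift. Of 40 cell cycle genes, 31 were above 0 (median log2 ratio 0.08, camera adjusted p = 0.00047, and 0.175 with an estimated correlation), and none passed over the list alone. Ccnb1, a mitotic cyclin, stood at 0.29 ± 0.17 (SD, n = 4) and the centromeric histone Cenpa at 0.22 ± 0.10. The median was 0.08 within slide 1 and 0.08 within slide 2, where the list did not pass. Nor did the list pass on the arrays with the labelled mutant in Cy5 (median 0.04, camera adjusted p = 0.414) or with scanner ratios (camera adjusted p = 0.0579). Of 34 p53 targets, 17 were above 0 and 17 below (median 0.00, camera adjusted p = 0.932), with Trp53inp1 at -0.43 ± 0.17 and Abhd4 at -0.24 ± 0.09.

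**Figure D3:**
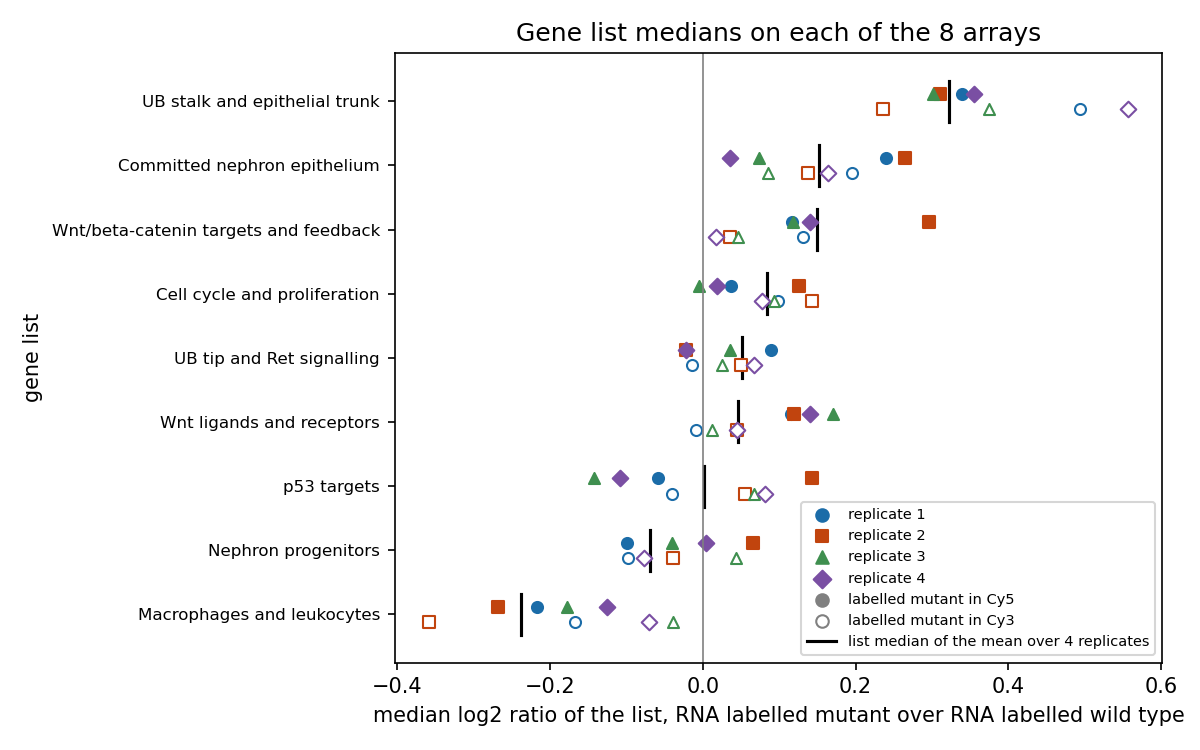
Median log2 ratio (x axis) of 9 gene lists (y axis) in the RNA labelled mutant over the RNA labelled wild type. Each symbol is 1 of the 8 arrays, filled with the labelled mutant in Cy5 and open in Cy3, and black bars are list medians of the genes' means over the 4 replicates. The UB stalk median is above 0 on 8 of 8 arrays, and the macrophage median below 0 on 8 of 8.

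Among the other cell types of the kidney, macrophage and leukocyte genes fell in the RNA labelled mutant. Of 17 measured genes, 15 were below 0 (median log2 ratio -0.24, camera adjusted p = 0.000117, 0.175 with an estimated correlation and 0.0531 with fry), on 8 of 8 arrays. On the arrays with the labelled mutant in Cy3 the Macrophages and leukocytes list did not pass (adjusted p = 0.136). Over the list alone, the complement gene C1qc, at -0.40 ± 0.18 (SD, n = 4), and the adaptor Tyrobp, at -0.33 ± 0.12, were lower, while the pan-leukocyte gene Ptprc stood at 0.27 ± 0.22. The median was -0.31 within slide 1 and -0.12 within slide 2, and -0.14 without replicate 2. The stalk and macrophage lists thus shifted in opposite directions.

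Lists of further cell types did not pass camera. The 25 stromal genes had a median log2 ratio of -0.07 (adjusted p = 0.794), yet over the list alone 2 were higher, among them Lef1, and 2 lower, among them Meis2 at -0.33 ± 0.02 (SD, n = 4), which turned to 0.10 with median centring in place of loess. The medians were 0.01 for 18 endothelial genes (adjusted p = 0.932; Robo4 at -0.26, Kdr at -0.19), -0.10 for 13 erythroid genes (0.551; Hbb-bh1 at -0.26, Alas2 at 0.08) and -0.05 for 18 neuronal and glial genes (0.229; Stmn2 at -0.43, Ngfr at -0.49). For 11 adrenal and gonadal genes the median was -0.02 (adjusted p = 0.952; Amh at 0.13, Akr1b7 at -0.12), and for 11 skeletal muscle genes -0.05 (0.569; Des at -0.25, Tnnt1 at -0.13). Differentiated nephron segments were no different, with medians of -0.02 for 15 podocyte genes (adjusted p = 0.932; Magi2 at -0.21), -0.09 for 21 proximal tubule genes (0.337; Lrp2 at -0.42, Ass1 at -0.28) and -0.13 for 11 genes of the loop and distal tubule (0.569; Wnk4 at -0.17, Ptger3 at -0.13). Another probe of Lrp2 stood at 0.00.

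Chromatin and silencing lists did not pass either. The 25 corepressor subunits had a median log2 ratio of -0.04 with 18 below 0 (camera adjusted p = 0.141; Rest at -0.28, Rbbp4 at -0.21 with probes from -0.49 to 0.14), and the 15 other deacetylases -0.02 (0.794; Sirt7 at -0.30, lower over the list alone, Sirt5 at 0.35). The 28 REST targets had a median of -0.04 (adjusted p = 0.229; Stmn2, and Syt1 at -0.40 with probes from -0.44 to 0.10), the 21 germline genes -0.01 (0.952; Hormad1 at -0.73, lower over the list alone, Rhox5 at 0.14) and the 36 Hox genes -0.04 (0.932; Hoxd1 at -0.37, Hoxb7 at 0.28).

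Growth control, stress and physiology lists did not pass camera, and among them the kidney injury list alone had members that passed over the list alone. CDK inhibitors had a median log2 ratio of 0.03 (10 genes, camera adjusted p = 0.952; Cdkn1c at -0.41, Cdkn2b at 0.26) and apoptosis regulators -0.05 (22 genes, 0.952; Bcl2l11 at -0.55). Kidney injury genes had a median of 0.01 (16 genes, adjusted p = 0.337), with 2 higher, among them Clu at 0.51, and Sox4 at -0.50 lower over the list alone. The medians were -0.05 for renin-angiotensin and bradykinin genes (15 genes, adjusted p = 0.794; Enpep at 0.79, Atp6ap2 at 0.25), 0.03 for extracellular matrix (23 genes, 0.337; Frem2 at 0.57, Col4a1 at 0.22), 0.01 for immediate early and heat shock genes (17 genes, 0.679; Hsph1 at 0.22, Ier2 at 0.11) and -0.04 for hypoxia and glycolysis (18 genes, 0.551; Vegfa at -0.16, Aldoa at -0.12). In 5 of the 32 lists (p53 targets, adrenal and gonad, CDK inhibitors, apoptosis, renin-angiotensin) the median and the camera test differed in sign. With an estimated correlation 0 of the 32 lists passed, and with fry 3 did: Wnt/beta-catenin targets (adjusted p = 0.00305), committed nephron (0.0381) and cell cycle (0.0381). The estimated correlation itself was 0.19 for the stalk and 0.011 for the macrophage list. It was -0.027 for committed nephron, -0.022 for Wnt/beta-catenin targets, -0.012 for cell cycle and -0.0066 for Wnt ligands and receptors. For the lists with an estimated correlation below 0, a correlation above the preset 0.01 does not account for the lost call. With an estimated correlation, camera takes its degrees of freedom from the 4 replicates and not from the genes, which lowers its power. A lost call is therefore not by itself a sign of correlated members.

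Sex-linked genes did not pass as a list, and none of them passed over the list alone. The 5 measured genes had a median log2 ratio of -0.41 (camera adjusted p = 0.218), with the Y-linked Eif2s3y at -0.51 ± 0.32 (SD, n = 4) and Xist, the RNA of the inactive X chromosome, at 0.52 ± 0.44. The mean of the 4 Y-linked genes was below 0 and Xist above 0 in 4 of 4 replicates.

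The authors' deposited table holds 226 positive and 270 negative log2 ratios. A one-sample t statistic over the 4 replicate means of the scanner ratios, at the thresholds in its name, selects 475 features, and these include 471 of the 494 features of the table. Of the 411 genes of the table that were tested here, 376 had the opposite sign by the dye labels, and 138 of them were at p under 0.05 and at least 1.4-fold in limma. None passed the adjusted threshold. The list was chosen on these samples, so the overlap is not independent evidence.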

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

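The tests for the slide, for an equal change of all UB genes, for labels turned on all arrays and for the sex of the embryos were chosen only after the result was seen. Of 118 groups of 4 values examined, 12 held a value far from the other replicates, where chance gives about 5.9.

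Regucalcin (Rgn) stood at a log2 ratio of 1.00 in replicate 4, against 0.83 to 0.85 in the others. Fxyd4 stood at 0.97 in replicate 3, against 1.38 to 1.44. Tfcp2l1 stood at 0.73 in replicate 2, against 1.01 to 1.05. Scin stood at 0.83 in replicate 1, against 0.63 to 0.64. Tcea3 stood at -1.07 in replicate 4, against -0.73 to -0.70. Wt1 stood at -0.14 in replicate 4, against -0.37 to -0.34. Ngfr stood at -0.93 in replicate 2, against -0.36 to -0.30. Abhd4 stood at -0.37 in replicate 2, against -0.20 to -0.19. The podocyte list had a median of -0.0355 in replicate 2, against -0.00904 to -0.00766, and the endothelial list -0.0405 in replicate 3, against 0.0376 to 0.0440. The REST target list had a median of -0.12 in replicate 2, against -0.00 to 0.01. In replicate 2, with the labelled mutant in Cy5, 79.2% of the spots were well above background in the RNA labelled wild type, against 94.6% to 97.1% in the other replicates. No biological explanation was tested for these values.

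The UB stalk list was higher in the RNA labelled mutant in camera, but lost that call with an estimated correlation (adjusted p = 0.175) and with fry (0.0531). A dye bias is argued against, since the lower of the mean list medians of both dye orientations was 0.33 (SD 0.02). A shift confined to 1 slide is argued against as well, since the lower slide median was 0.31, beyond the SD of the replicate medians of 0.04. A bias that both slides share would not show in that test. An equal change of all bud genes is argued against by the UB tip list, although tip genes are also expressed outside the bud. Its mean lay 0.31 (log2) below that of the stalk list, and 0.19 to 0.45 below it in the 4 replicates. A permutation of genes between both lists gave p = 0.00418. It treats genes as independent, while stalk genes had an estimated correlation of 0.19, so this p does not measure the spread over replicates. Of 35 splits of the 8 RNA samples, 1 gave a median as large (the real one, 0.32; highest other 0.29). Since the RNAs are paired by their arrays, the real split compares with the 8 that part every pair. Of these, 1 reached 0.32 (highest other 0.22), and 8 are too few for a share under 0.05. A change in the composition or state of the bud stays open and untested. Whole kidney RNA cannot place the shift in the bud rather than in other epithelium, and the committed nephron list also had a median above 0 (0.15). The shift would run the other way if the authors' deposited table is written as mutant over wild type.

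The opposite signs of the dye labels and of the authors' deposited table stay unexplained. Labels wrong on some of the arrays are argued against, since the stalk list's median was above 0 on 8 of 8 arrays, with a lowest value of 0.24. Whether the labels are turned on all arrays cannot be told apart from a table written as wild type over mutant, since the mean Hdac2 ratio of 0.26 (SD 0.47) lay within its spread.

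The Y-linked mean was -0.55, -0.46, -0.16 and -0.45 and Xist 0.77, 0.13, 0.17 and 1.01 in replicates 1 to 4. Both had opposite signs in 4 of 4 replicates, which is consistent with a larger share of female tissue in the RNA labelled mutant. A dye bias is argued against, since the Y-linked mean had the same sign on both arrays in 4 of 4 replicates. Whether sex adds to other differences was not tested.

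For single genes the splits are too few as well. The real signs gave 224 genes at an unadjusted p under 0.05 and at least 1.4-fold, the largest count in 1 of 8 sign patterns (highest other 157), which cannot give a share under 0.05. With unpaired channels, 24 of 35 splits gave as many as the real 196 genes (highest other 4122, and 100 among the splits that part every pair). At an adjusted p the real count with unpaired channels was 0 genes by limma, with 534 at an unadjusted p under 0.05, so 35 of 35 splits reach it whatever the data, which tests nothing. The split with the highest count, 5524 genes, parts replicates 1 and 2 from 3 and 4, which are the slides, and points to a structure of the samples. Splits that part every pair gave 0 genes. Within slide 2 limma called 38 genes higher and 66 lower, and within slide 1 it called 0 with 504 at an unadjusted p under 0.05.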

How the results depend on the processing

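The alternatives were chosen before the data were examined. Hdac2 kept its sign and stayed short of the threshold under each of them, at 0.14 to 0.49 with each replicate left out, and the UB stalk list kept its sign and passed camera at the preset correlation under each of them (medians 0.27 to 0.55), but not with an estimated correlation or fry. The direction of the 24 named genes at the ends of the ranking held under each alternative, except that the strict filter left 23 of them and gave no value for Lyzl1. All replicates of each of these genes share a sign. Leaving out a replicate, single slides and array weights therefore could not turn their direction and do not test it. The cause was not tested for the changes below.

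Limma called 0 genes higher and 0 lower in the main setting, with 1839 at an unadjusted p under 0.05. The replicate block over 8 arrays gave 58 higher and 16 lower, the replicate block with a dye term 38 and 11, 8 arrays as independent 52 and 15, and array weights 58 and 20; these treat the arrays of a replicate as more samples or weigh replicates unequally. Agilent processed signals gave 1 and 1, scanner ratios 2 and 1, median centring 6 and 1, the arrays with the labelled mutant in Cy5 alone 0 and 1, and slide 2 alone 38 and 66. Leaving out each replicate gave 0 to 9 higher and 0 to 2 lower, the most without replicate 2. Separate channels with no replicate block changed neither count.

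Genes at an unadjusted p under 0.05 and at least 1.4-fold numbered 107 higher and 117 lower. They were 218 and 438 with processed signals, 280 and 340 with scanner ratios, 840 and 84 with median centring (90.9% higher against 47.8%), 207 and 462 on the Cy5 arrays, 512 and 541 on the Cy3 arrays, 92 and 196 with array weights, 215 and 165 in slide 1, and 99 and 419 in slide 2. A plain t statistic gave 56 lower. Leaving out each replicate gave 91 to 140 higher and 88 to 338 lower. The shared genes with the authors' deposited list (opposite sign) numbered 138, against 301 with processed signals and 328 with scanner ratios, and the shared genes with the authors' deposited list (same sign) 1 on the Cy3 arrays.

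Of the 6 lists called, camera with an estimated correlation left 0 and fry 3, while median centring gave 13 and the Cy3 arrays 2. With an estimated correlation the adjusted p was 0.175 for the UB stalk, committed nephron, Wnt/beta-catenin target, cell cycle and macrophage lists and 0.219 for Wnt ligands and receptors. With fry it was 0.0531 for the stalk and macrophage lists and 0.392 for Wnt ligands and receptors. The cell cycle list missed the threshold of camera's adjusted p with scanner ratios (median 0.0877, adjusted p = 0.0579). It also missed it on the Cy5 arrays (median 0.0423, adjusted p = 0.414) and in slide 2 (median 0.0775, adjusted p = 0.0681). With median centring the UB tip list passed camera at a median of 0.17, and the nephron progenitor median turned to 0.16 and passed (adjusted p = 0.0341). The Wnt ligand list missed the threshold there (median 0.0397, camera adjusted p = 0.0519). On the Cy3 arrays the committed nephron (median 0.14), Wnt target (median 0.0933) and macrophage (median -0.17) lists missed camera's threshold. The Wnt ligand median turned to -0.0329 on them. The Wnt ligand list missed the threshold in slide 1 (median 0.00938, camera adjusted p = 0.212), and its median ranged from 0.0122 to 0.0843 with each replicate left out. In slide 2 the nephron progenitor median turned to 0.00446. The p53 target median, 0.00 in the main setting, turned to -0.0256 with the mean of probes, -0.0895 on the Cy5 arrays, -0.0456 with array weights and -0.0273 in slide 2, and ranged from -0.0409 to 0.0222 with each replicate left out.

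Of 1721 values of 82 named genes under the alternatives, 20 had the opposite sign, in 16 genes. With median centring Wt1 turned to 0.0246, Meis2 to 0.0957, Robo4 to 0.0436, Kdr to 0.0847, Hbb-bh1 to 0.0201, Akr1b7 to 0.0342, Tnnt1 to 0.0703, Abhd4 to 0.0846, Cdkn1c to 0.0752, Rest to 0.00248, Rbbp4 to 0.17, Vegfa to 0.0740 and Aldoa to 0.33. On the Cy5 arrays Sirt7 turned to 0.0963 and Vegfa to 0.15, and on the Cy3 arrays Magi2 to 0.0495, Ptger3 to 0.0848, Akr1b7 to 0.0852, Abhd4 to 0.0302 and Aldoa to 0.0411. By size, scanner ratios made 8 named genes over 1.5 times larger, among them Rgn, Lyzl1, Dapl1, Cdkn2b and Stmn2, and 10 smaller by over that factor. Processed signals made 9 larger and 11 smaller, and median centring 12 larger and 27 smaller or opposite. Hdac1 has no value, so its alternatives were not run. Signal over background limits dim genes such as Lyzl1, well above background on 5 of 8 arrays in the RNA labelled mutant.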

Other observations

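The tests of both lists were chosen only after the result was seen, on the genes of the same arrays. Aldh1a3 and Stra6 were among the genes lowest in the RNA labelled mutant, so a list of retinoid synthesis, transport and response genes was tested without them. Of the 21 genes left, 17 were below 0 (median log2 ratio -0.04, camera p = 0.112, and p = 0.301 with an estimated correlation), so a shift of the list beyond the genes that prompted it was not shown. Among them Aldh1a1, another enzyme of retinoic acid synthesis, stood at -0.95 ± 0.39 (SD, n = 4). The receptors Rara, Rarb and Rarg stood at -0.01, 0.05 and -0.01, and Cyp26a1, which degrades retinoic acid, at 0.02. In the authors' deposited table, which states no direction, Stra6 has a log2 ratio of 1.15.

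Shh, the Hedgehog ligand of the bud stalk, stood at 0.62 ± 0.14 (SD, n = 4) and did not pass over all genes (limma, adjusted p = 0.184). Over the 16 other measured Hedgehog pathway genes, 8 were above 0 and camera gave p = 0.840 (0.898 with an estimated correlation), so a shift of the pathway was not shown. The target genes Gli1 and Ptch1 stood at 0.09 and 0.02.

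Across genes, which are not independent replicates, the replicate log2 ratios correlated at -0.14 between replicates 1 and 2 and at 0.37 between replicates 3 and 4, each pair on the same slide. Between slides they correlated at 0.27 for replicates 2 and 3, -0.00921 for 1 and 3, 0.06 for 1 and 4 and -0.01 for 2 and 4. The dye orientations of a replicate, both turned to labelled mutant over labelled wild type, correlated at 0.07, 0.70, -0.28 and -0.30 in replicates 1 to 4. The dye part, which cancels in the replicate mean, correlated at up to 0.82 between replicates.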
